A study of Arabidopsis thaliana with 8 samples.

How the data were processed

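The study holds 8 arrays of total RNA from aerial parts of 10-day-old 35S::FLAG-GR-rREV seedlings after 2 h with mock, 6-BA, DEX or 6-BA+DEX, with 2 biological replicates in each of 4 groups. Each file is the scanner output of 1 array of an Agilent Arabidopsis design with Cy3 as its 1 colour. The intensity of each spot was background-subtracted and detrended within the array by Agilent Feature Extraction 10.7.1.1 before it was deposited, per the file headers. Raw mean spot intensity and median local background intensity are in the same files, per the file headers. The deposited series matrix holds log2 values whose making is not stated. Set against the arrays, its columns had a lowest r of 0.997 with log2 of its own array's processed signal and nearly the same sorted values as the others, with medians of 8.14, and it served as an alternative only. Its values are not centred and their scale is log2, as this comparison shows.

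Per array, 43803 spots remained without 1417 control spots. Outlier spots were left out, spots of a probe were averaged to 43603 probes, and 126 probes without a value on every array were dropped. Log2 of the processed signal was taken minus each array's 75th percentile. Kept were 29721 probes well above background on both arrays of at least 1 group, and the brightest probe over all arrays stood for a locus, giving 21969 loci or unnamed probes, of which 19292 have a locus. Probe names came from the accessions of the array design matched to the annotation of the assembly TAIR10.1, which was used for names only: 34358 probes matched by accession, 2137 by the design's name alone, and 7108 had no locus. Probes whose accessions name several loci stood for 183 of the tested loci. Where a locus had other kept probes, disagreement is given beside its value.

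Groups were compared in limma 3.58.1 under R 4.3.3 with lmFit and eBayes, 1 mean per group, all 8 arrays sharing an estimate of the spread. The 8 contrasts were 5 between pairs of groups, the average 6-BA effect, the average DEX effect and their interaction. A call needed a Benjamini-Hochberg adjusted p under 0.05 over all loci and a change of at least 1.5-fold. The submitters' notes name a 1.5-fold difference with an unadjusted p under 0.05, and counts at that criterion are given. Where no locus responds, a share of about 0.05 would have an unadjusted p under 0.05 before the fold limit. These are therefore not counts of responding loci. A probe on no array of a group well above background has a bound there: the bright side's mean against the higher, per array, of the lowest signal among probes well above background and the probe's own.

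The replicate numbers were checked for pairing. Deviations from group means correlated between same-numbered arrays in every pair of groups, with r between 0.486 and 0.625, and each number shares a slide and a scan day, so the numbers pair the samples. The fit with the replicate number as a block was therefore given beside each result that it changes. Slide and scan day as blocks are the same fit. Treatment and position on the slide cannot be told apart.

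Before the data were examined, 26 gene lists with 298 loci, the contrasts, the alternatives and the rule for named genes were fixed. Of the list loci 292 were on the array. Lists were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over 208 tests of lists and contrasts, again with an estimated correlation, and with fry. With an estimated correlation camera has at most the residual degrees of freedom of the fit, 4, or 3 with the replicate block. That leaves it little power here, so a list that fails it is left undecided. The lists cover type-A and type-B response regulators, cytokinin receptors and phosphotransfer proteins, cytokinin degradation and conjugation, cytokinin synthesis and activation, cytokinin-responsive transcription factors and effectors, HD-ZIP III, LITTLE ZIPPER and HD-ZIP II genes, auxin synthesis, transport and early response, shoot meristem and boundary genes, abaxial polarity, ABA receptors and phosphatases, ABA and drought response, shade avoidance and brassinosteroid bHLH genes, gibberellin metabolism, ethylene synthesis, cell cycle, nitrate, touch and wounding, heat shock, xenobiotic response, circadian clock and root markers. The text draws on up to 10 higher and 10 lower loci per contrast by size among called loci that changed alike on both slides, filled with loci called with the replicate block alone and named as such, or the 5 smallest p where none was called. From these and the called list members it names about 20 to 30 per main comparison, list members first, along with every measured HD-ZIP III, LITTLE ZIPPER and type-A gene.

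Alternatives were quantile normalization, centring on the median of kept probes, normexp background correction with an offset of 50, no filter on dim probes, a filter for probes well above background on all 8 arrays, the replicate block, the deposited matrix, a fit of each contrast's groups alone, the mean of probes, trend and robust moderation, the adjusted p alone, the submitters' criterion, a plain unmoderated test per locus, and each array left out. The fits were tested on simulated values built from the normalized and filtered arrays, so scaling, filtering and choice of probe were not tested. Each locus kept its slide difference, with independent noise at the spread of the fit with the replicate block. This noise has the form that the replicate block assumes, so the recovery may not carry over to the real data. For the average 6-BA effect the main model recovered 29.9%, 80.6% and 92.4% of loci changed 2-fold, 4-fold and 8-fold among 21969, with 0 false calls, and the replicate block recovered 79.1%, 92.5% and 100% with 7 false calls. For 6-BA against mock these were 4.48%, 67.2% and 83.3% with 1 false call, and 53.7%, 88.1% and 100% with 14. Simulated unchanged groups sharing control arrays were drawn 20 times, from the spread within groups, and 20 times more with each locus's slide difference kept and the spread of the fit with the replicate block. Figures were made with matplotlib 3.10.9 under Python 3.11.15.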

Results

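Transcript levels were measured in the aerial parts of 10-day-old Arabidopsis seedlings that carry 35S::FLAG-GR-rREV. This transgene encodes REVOLUTA (REV), a class III homeodomain leucine zipper (HD-ZIP III) transcription factor, fused to the hormone-binding domain of the glucocorticoid receptor, so that dexamethasone (DEX) moves the fusion into the nucleus. Seedlings were treated for 2 h with solvents alone (mock), with the cytokinin 6-benzylaminopurine (6-BA), with DEX, or with both compounds (6-BA+DEX). Each of the 4 groups had 2 biological replicates, each on its own 1-colour array, giving 8 arrays. Replicate 1 of every group was on slide 1 and replicate 2 on slide 2, and each treatment had the same position on both slides. Between 61.6% of the spots (6-BA+DEX replicate 2) and 71.1% (mock replicate 2) were well above background, and DEX replicate 2 had 63.8%. No plants without the fusion were analysed here, so responses to DEX itself cannot be told apart from those to nuclear REV. The number of arrays limits the precision of every value.

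REV itself was bright on all arrays, with a log2 signal above the array's 75th percentile of 4.10 ± 0.17 (SD, n = 2) in mock and 4.03 ± 0.13 (SD, n = 2) with DEX. Its average DEX effect was -0.01 ± 0.14 (log2, SE). The probe cannot tell the transgene from the native gene. The other HD-ZIP III genes measured, PHB, PHV, CNA and ATHB8, had average DEX effects of 0.05, -0.15, -0.20 and -0.37, and average 6-BA effects of -0.17, -0.21, -0.26 and 0.05. None of the 5 HD-ZIP III genes passed limma's test for either effect, over all loci or adjusted over the list alone.

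The first principal component held 43.4% of the variance, and every array of slide 1 had a negative score on it while every array of slide 2 had a positive one. Within each slide the arrays with DEX scored higher on it than those without. On slide 2 DEX had 53.2 and 6-BA+DEX 68.5, against 0.90 for mock and 13.6 for 6-BA. These 2 arrays with DEX had the fewest spots well above background, so this component does not follow the slide alone. The second component (17.7%) put the DEX and 6-BA+DEX arrays above the other arrays, and the third (14.2%) separated the arrays with 6-BA from those without. Between the slides, 2516 of 21969 loci differed, 845 higher and 1671 lower on slide 2. For this reason values with the replicate number as a block (replicate block) stand beside the main ones wherever they change a call.

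**Figure D1:**
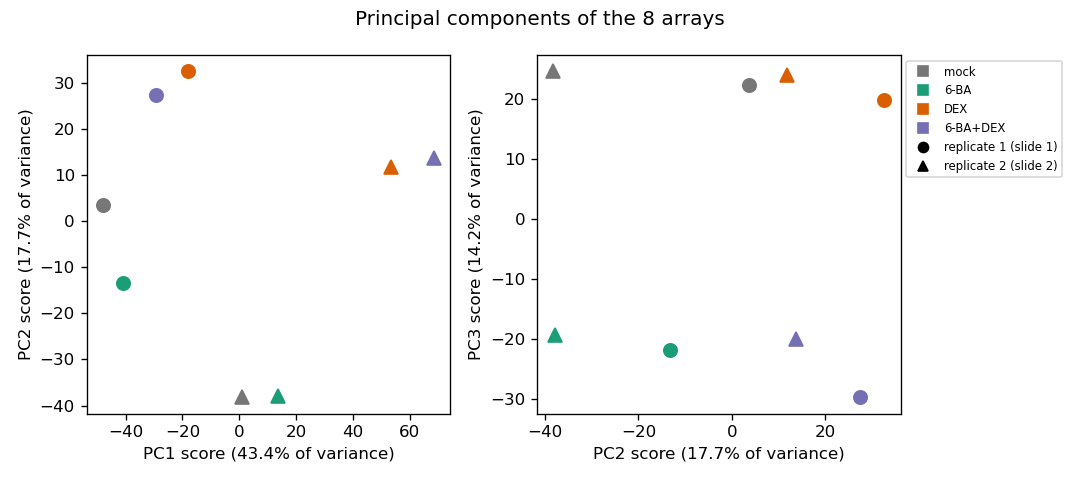
Scores of the 8 arrays on principal components 1 and 2 (left) and 2 and 3 (right), with the share of variance on each axis, treatments in colour and replicates by symbol. Component 1 (43.4%) parts the slides and, within each slide, is higher in the arrays with DEX. Component 2 (17.7%) parts arrays with and without DEX, and component 3 (14.2%) parts arrays with and without 6-BA.

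The average 6-BA effect compares 4 arrays with the cytokinin against 4 without, with and without DEX alike, and asks which transcripts respond to cytokinin. Of the 7 loci that limma called higher over all loci, 5 were type-A response regulators, cytokinin-induced repressors of cytokinin signalling. ARR15 rose by 3.52 ± 0.26 (log2, SE, limma adjusted p = 0.0305), ARR5 by 2.87 ± 0.18 (adjusted p = 0.0238), ARR6 by 2.42 ± 0.15 (adjusted p = 0.0238), ARR7 by 2.25 ± 0.16 (adjusted p = 0.0273) and ARR16 by 2.18 ± 0.14 (adjusted p = 0.0238). AT1G68360 rose by 2.20 ± 0.14 and GLP7, a germin-like protein gene, by 1.67 ± 0.13 (adjusted p = 0.043), while AACT1 fell by 2.34 on the log2 scale (adjusted p = 0.0273). Over all loci limma called 8, 7 higher and 1 lower, and with the replicate block 75, 59 higher and 16 lower.

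All 9 type-A response regulators measured rose when adjusted over the list alone, among them ARR4 (1.94), ARR17 (1.69), ARR9 (1.39) and ARR8 (1.15), and over all loci 5 did. Camera placed the list above other loci (adjusted p = 1.16e-22), with adjusted p = 0.175 with an estimated correlation. Of 9 genes of cytokinin degradation and conjugation, 6 rose adjusted over the list alone. These include the cytokinin oxidase genes CKX3, at least 4.63-fold higher because no array without 6-BA measured it well above background, CKX4 (1.30), CKX5 (1.22), CKX6 (0.77) and CKX7 (0.70), and UGT76C2 (1.55), which encodes a cytokinin glucosyltransferase. For that list camera gave adjusted p = 1.68e-09, and adjusted p = 0.175 with an estimated correlation. Of 11 cytokinin-responsive transcription factors and effectors, 6 rose adjusted over the list alone: CRF2 (1.39), CRF5 (1.46) and CRF6 (0.77) of the cytokinin response factors, GATA22 (0.84), ASL9 (2.07) and the expansin gene EXPA1 (0.95). All 11 had positive values, with camera adjusted p = 2.47e-10 and adjusted p = 0.175 with an estimated correlation.

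**Figure D2:**
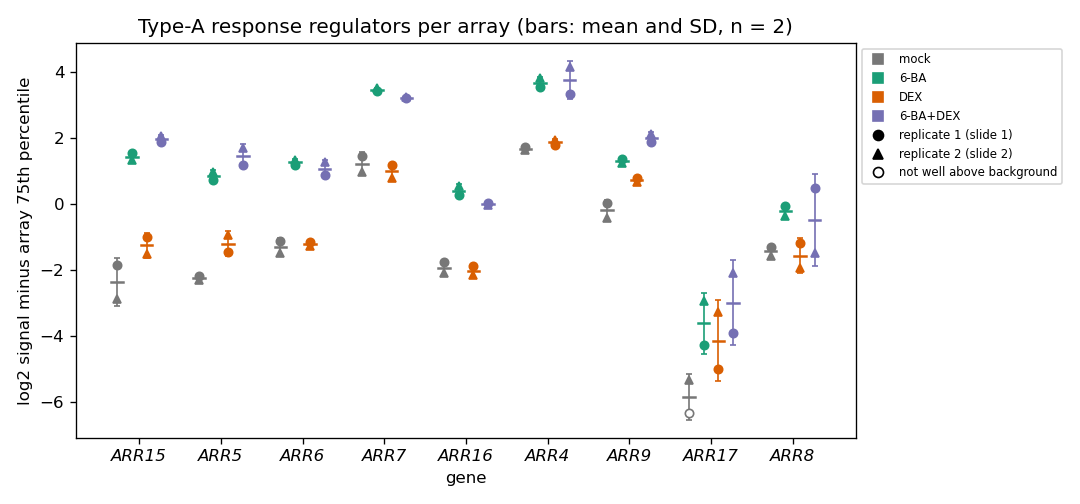
Log2 signal minus the array's 75th percentile of the 9 type-A response regulators measured (x axis), per array, with group means and SD (n = 2). For ARR5 the mock arrays lie at -2.20 and -2.29, the 6-BA arrays at 0.72 and 0.97.

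Of 7 cytokinin receptors and phosphotransfer proteins, the receptor gene AHK4 alone rose adjusted over the list alone (1.55 ± 0.37), and camera did not place that list apart (adjusted p = 0.873). None of the 7 type-B response regulators passed adjusted over the list alone, though the list's median was -0.37 (-0.13 with 1 gene near background at its bound) and camera placed it below other loci (adjusted p = 0.015; adjusted p = 0.271 with an estimated correlation; 0.0887 with normexp). Of 8 genes of gibberellin metabolism, the synthesis genes GA20OX1 (1.01 ± 0.20) and GA20OX2 rose adjusted over the list alone. GA20OX2 was at least 1.55-fold higher, well above background on 3 arrays with 6-BA and 2 without, and its sign turned with normexp (-0.06). GA20OX3 rose too with the replicate block, at least 1.13-fold and well above background on 2 arrays with 6-BA and 1 without (blocked adjusted p = 0.044). That list lay above other loci (camera adjusted p = 0.00328; adjusted p = 0.191 with an estimated correlation; 0.145 with normexp), and its median of 0.80, or 0.53 with 2 genes near background at their bounds, was 0.00 with normexp. Of 7 shade avoidance and brassinosteroid bHLH genes, BEE1 rose adjusted over the list alone (0.61 ± 0.15), with camera adjusted p = 0.246.

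Loci called for the average 6-BA effect with the replicate block alone include AT3G61920, with 2.46 (blocked adjusted p = 0.0393), and AT3G50300, at least 3.31-fold higher (blocked adjusted p = 0.0456). On the lower side they include NAC047, with -1.52, where another probe of the locus gave 0.28, and EXL4, AT5G18130 and AT5G42680, with -1.28, -1.16 and -1.14. In the fit without the block, the calls were lost with each of the 8 arrays left out in turn, while ARR15 kept values between 3.26 and 3.78.

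Against mock, 6-BA alone gave ARR15 a change of 3.81 ± 0.37, ARR5 3.09 ± 0.26, ARR6 2.57 ± 0.21 and ARR16 2.34 ± 0.19 (log2, SE, 2 arrays against 2). With the replicate block these 4 rose, with blocked adjusted p = 0.0491, 0.04, 0.0498 and 0.0491, as did GLP7 (1.95), and AACT1 fell (-2.39, blocked adjusted p = 0.04). GA20OX3 (2.36, blocked adjusted p = 0.04) was well above background on both 6-BA arrays and 1 mock array. Without the block limma called 0 loci, against 602 at an unadjusted p under 0.05 with a 1.5-fold change, and 15 with the replicate block, 11 higher and 4 lower. At any size of change, 983 of 21969 loci had an unadjusted p under 0.05 without the block, a share under 0.05. Adjusted over the list alone, 8 of 9 type-A regulators rose, the exception being ARR8 (1.22). Against DEX alone, 6-BA+DEX gave ARR15 3.23, ARR5 2.65, ARR6 2.28 and ARR7 2.25, and 7 of the 9 regulators rose adjusted over the list alone. That comparison gave 0 calls over all loci with limma, 594 at an unadjusted p under 0.05 with a 1.5-fold change, and 1 with the replicate block, AT4G09300, at least 2.55-fold lower, whose probe was well above background in the DEX arrays and in neither 6-BA+DEX array. There 1051 of 21969 loci had an unadjusted p under 0.05 at any size of change, again a share under 0.05.

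The average DEX effect compares 4 arrays with active REV fusion against 4 without. Adjusted over the list alone, 2 of 3 genes for LITTLE ZIPPER proteins, small partners of HD-ZIP III factors, and 5 of 9 for HD-ZIP II factors rose, and the abaxial polarity genes KAN1 and KAN2 fell. ZPR3 rose by 2.97 ± 0.38 and ZPR1 by 2.77 ± 0.42 (log2, SE), adjusted over the list alone (limma adjusted p = 0.000679 and 0.000902), while ZPR2, the other member measured, was not called and was well above background on 1 of 4 DEX arrays. Over all loci they had adjusted p = 0.0728 and 0.11, and with the replicate block 0.0315 and 0.0209. Among loci called over all loci, BBX31, a B-box gene, rose by 2.88 ± 0.26 (adjusted p = 0.0438), AT5G47250 by 1.91 ± 0.11 (adjusted p = 0.0397), AT1G55760 by 1.79 ± 0.12 (adjusted p = 0.0397), the beta-glucosidase gene BGLU28 by 1.74 ± 0.15 (adjusted p = 0.0438) and AT5G47130 by 1.71 ± 0.16 (adjusted p = 0.0438), and CLC-B, of the chloride channel family, fell by 1.60 on the log2 scale (adjusted p = 0.0438).

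Of 9 HD-ZIP II genes, 5 rose adjusted over the list alone: ATHB2 (1.77), ATHB4 (1.67), HAT14 (1.23), HAT1 (0.88) and HAT22 (0.62). The list lay above other loci (camera adjusted p = 0.000218; adjusted p = 0.175 with an estimated correlation), as did the LITTLE ZIPPER list (adjusted p = 0.00185; adjusted p = 0.188 with an estimated correlation). In auxin synthesis, TAA1 (1.24 ± 0.13) and YUC5 (0.72 ± 0.15) rose adjusted over the list alone among 9 genes, without a camera call (adjusted p = 0.28), though with normexp the list passed as higher (adjusted p = 0.0245; adjusted p = 0.625 with an estimated correlation). Of 9 abaxial leaf polarity genes, KAN1 (-1.90 ± 0.30) and KAN2 (-0.83 ± 0.21) fell adjusted over the list alone, and camera placed the list below other loci (adjusted p = 0.0155; adjusted p = 0.562 with an estimated correlation). The list's median shrank from -0.36 to -0.15 with normexp (camera adjusted p = 0.00732), and for DEX against mock from -0.39 to -0.07, but for 6-BA+DEX against 6-BA it was -0.26 and -0.24. With the replicate block KAN3 (-0.91) fell too, adjusted over the list alone.

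Genes of gibberellin metabolism moved both ways. GA20OX1 fell (-1.74 ± 0.20), as did GA20OX2, at least 1.54-fold and measured well above background on 1 of 4 DEX arrays, and GA2OX2 (-1.21), while the synthesis gene GA3OX1 rose (0.89), each adjusted over the list alone. GA20OX3 fell with the replicate block (blocked adjusted p = 0.0243), but it was well above background on no DEX array and on 3 without, so no fold is given, and its sign turned with normexp (0.07). GA20OX2 turned its sign with normexp (0.21), and another probe of GA2OX2 gave 0.18. Camera placed the 8 genes below other loci (adjusted p = 0.000844; adjusted p = 0.175 with an estimated correlation). Their median was -1.01, or -0.79 with 2 genes near background at their bounds, and -0.13 with normexp (camera adjusted p = 0.0192). For DEX against mock it turned from -1.05 to 0.15 with normexp, and camera's adjusted p rose from 0.00083 to 0.126 (0.175 and 0.696 with an estimated correlation). Of 7 shade avoidance and brassinosteroid bHLH genes, PIL1, at least 2.16-fold lower, and BEE1 (-0.68) fell adjusted over the list alone, with camera adjusted p = 0.00109 and adjusted p = 0.175 with an estimated correlation. Of 16 ABA receptors and PP2C phosphatases, the phosphatase gene ABI1 (0.85) and the receptor gene PYL6 (0.70) rose adjusted over the list alone (camera adjusted p = 0.0583).

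In the cytokinin pathway, CRF2 (-0.84) and EXPA1 (-0.60) fell adjusted over the list alone with DEX, and camera placed their list of 11 genes below other loci (median -0.31, or -0.06 with normexp, adjusted p = 0.00742; adjusted p = 0.415 with an estimated correlation). UGT76C2 fell too, adjusted over the list alone (-0.995), while 2 type-A regulators rose, ARR5 (0.83) and ARR9 (0.81), and with the replicate block 4, including ARR15 (0.83) and ARR17 (1.16). For the lists of UGT76C2 and of these regulators camera gave adjusted p = 0.0602 (0.0372 with the replicate block; adjusted p = 0.636 with an estimated correlation) and 0.166. For DEX against mock camera placed them below (adjusted p = 0.0162; adjusted p = 0.476 with an estimated correlation) and above other loci (adjusted p = 0.0258; adjusted p = 0.536 with an estimated correlation), and neither passed with normexp (0.12 and 0.124). With the replicate block, adjusted over the list alone, 3 of 27 Aux/IAA and GH3 genes of the early auxin response fell, GH3.3 (-1.11), GH3.17 (-1.11) and IAA29 (-0.73), and IAA13 (0.61) rose. Likewise RD29A (-1.45), COR15A (-1.61) and KIN1 (-0.70) of 7 genes of ABA and drought response fell, and IPT3 (-0.86) of cytokinin synthesis.

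**Figure D3:**
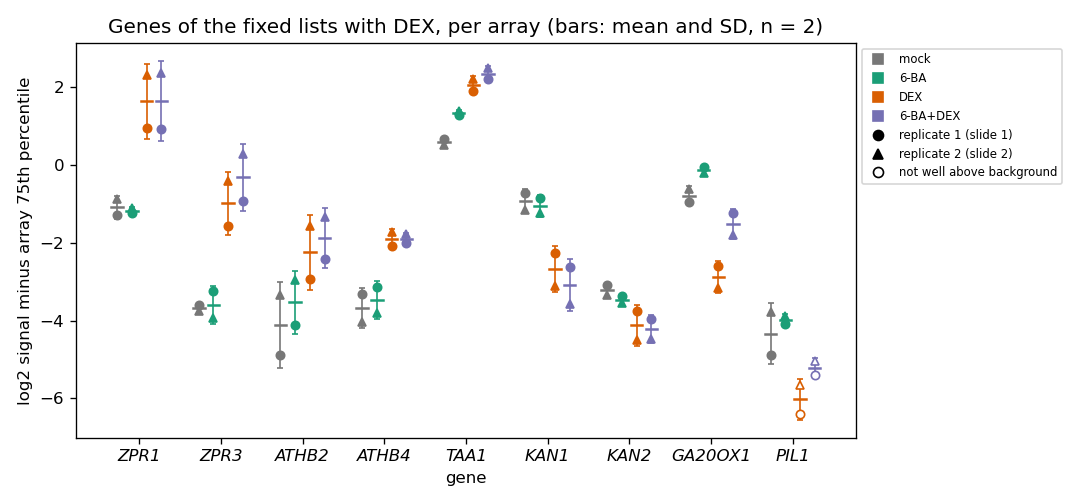
Log2 signal minus the array's 75th percentile of 9 genes of the fixed lists (x axis), per array, with group means and SD (n = 2), open symbols not well above background. For KAN1 the mock arrays lie at -0.72 and -1.16, the DEX arrays at -2.27 and -3.10.

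Over all loci limma called 19 for the average DEX effect, 16 higher and 3 lower, and with the replicate block 500, 305 higher and 195 lower. Among the 19, RABA1e was at least 3.39-fold higher, and AT2G22940, AT4G28790, EG505112 and A_84_P766924 were at least 1.57-fold, 1.93-fold, 1.89-fold and 1.20-fold higher, each of the last 4 measured well above background on 2 of the 4 DEX arrays and on none without DEX. For AT2G22940 and A_84_P766924 those 2 were the 6-BA+DEX arrays, and no array with DEX alone measured them well above background. AT3G60470, well above background on 3 arrays without DEX, was at least 1.21-fold lower, and AT5G55450 at least 1.02-fold lower, with a sign that turned under normexp (0.23). Loci called with the replicate block alone include AT1G10585 (-2.95), JMT (-2.14), which encodes a jasmonate methyltransferase, AT5G05965 (-2.01) and AT1G11925, at least 2.02-fold lower. Leaving out any of the 8 arrays ended all 19 calls, with BBX31 between 2.69 and 3.08 and a lowest adjusted p between 0.0647 and 0.212.

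Against mock, DEX alone gave ZPR1 2.72 ± 0.60, ZPR3 2.68 ± 0.54, TAA1 1.47 ± 0.18, ATHB4 1.77 ± 0.34 and GA20OX1 -2.10 ± 0.28 (log2, SE, 2 arrays against 2), each past the test adjusted over the list alone. Against 6-BA alone, 6-BA+DEX gave ZPR1 2.81, ZPR3 3.27, TAA1 1.01, ATHB4 1.57, KAN1 -2.04 and GA20OX1 -1.39, likewise past that test. Over all loci DEX against mock had 0 calls with limma, 944 at an unadjusted p under 0.05 with a 1.5-fold change, and 5 with the replicate block. Those 5 were AT4G09300, AT2G37820 and RABA1e, at least 5.06-fold, 4.74-fold and 4.45-fold higher, DD11, at least 1.44-fold lower, and AT3G60470, lower with no fold given, as it was well above background on 1 mock array and no DEX array. For 6-BA+DEX against 6-BA the counts were 0, 824 and 9, with RABA1e at least 2.58-fold higher and AT3G60470 at least 2.06-fold lower among the 9.

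With both compounds against mock, ARR15 rose by 4.35 ± 0.37, ARR5 by 3.70 ± 0.26, ARR6 by 2.37 ± 0.21 and ARR9 by 2.20 ± 0.20 (log2, SE, limma adjusted p = 0.0484, 0.0484, 0.0484 and 0.0488), along with AT5G47130 (2.49), while AACT1 fell (-2.68). The call of the 15 loci, 13 higher and 2 lower, grew to 183 with the replicate block, 112 higher and 71 lower, among them TAA1 (1.76), ATHB2 (2.24), KAN1 (-2.16), ARR17 (2.85), GH3.17 (-1.83) and the nitrate transporter gene NRT1.7 (-2.53). AT2G22940, at least 9.05-fold higher, A_84_P766924, TA49656_3702, A_84_P766026 and AU231096, at least 5.24-fold, 2.92-fold, 2.33-fold and 3.68-fold higher, had signal well above background in the 6-BA+DEX arrays and in none of the mock arrays. Both responses were present: adjusted over the list alone, ZPR1 (2.73), ZPR3 (3.34), CKX3 (at least 7.71-fold), CKX5 (1.55), CRF5 (1.52) and GA3OX1 (1.70) rose, and the type-B regulator ARR2 (-0.67) fell. The 15 calls ended with each of the 8 arrays left out, and with normexp or without the filter on dim probes. With an array left out ARR15 kept values between 3.83 and 4.87, ARR5 between 3.44 and 3.96 and ARR6 between 2.17 and 2.56, and the lowest adjusted p lay between 0.074 and 0.236.

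The title of the series asks for genes that cytokinin and HD-ZIP III factors regulate together. No locus was called in the same direction in 6-BA+DEX against each single treatment by limma's adjusted test, with or without the replicate block. After quantile normalization there were 3, AT2G22940, A_84_P766924 and AU231096, each well above background in the 6-BA+DEX arrays and on no array of the other groups compared. At an unadjusted p under 0.05 with a 1.5-fold change there were 53 higher and 61 lower, against 88.2 and 90.2 in simulated unchanged groups that share the 6-BA+DEX arrays, and 7.01 and 4.24 in independent lists. That simulation leaves out the difference between the slides. One that keeps each locus's slide difference, run after the data were seen, gave 13.5 and 13.5. Members of the fixed lists among the 53 were the type-A regulator ARR9, with 0.70 against 6-BA and 1.29 against DEX, and IAA30, with 0.92 and 1.12. ARR9 was well above background on 8 arrays and IAA30 on 6. Well above background on all arrays were 25 of the 53 and 61, such as AMP1, with 0.99 against 6-BA and 1.13 against DEX, and AT5G47130, with 2.28 and 1.35, both picked after their values were seen. For the interaction, the departure from additive log2 effects, limma called 0 loci, and 220 at an unadjusted p under 0.05 with a 1.5-fold change, and 0 with the replicate block. At any size of departure 230 of 21969 had an unadjusted p under 0.05, far below a share of 0.05. The smallest p belonged to NP036270, DD11, AT2G22940, AT3G61660 and A_84_P766924, with adjusted p between 0.469 and 0.564. Each of these was well above background in at most 2 of the 4 groups, so no fold is given.

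Across loci, which are not independent replicates, the average 6-BA and average DEX effects had Pearson's r = 0.05 (Spearman's rho = 0.03), with -0.274 under normexp and 0.270 without the filter on dim probes. Taking the effects from different slides gave r = -0.11 and 0.13. The 6-BA effects without and with DEX, from disjoint arrays, had r = 0.315 (rho = 0.522), and the DEX effects without and with 6-BA r = 0.497 (rho = 0.664), or 0.610 and 0.751 on probes well above background on all 8 arrays. For 6-BA and DEX each against the shared mock arrays, r was 0.342 and the covariance 0.0598, against 0.498 and 0.0700 in simulated unchanged groups, and 0.502 and 0.0303 with the slide difference kept. With the replicate block, 12 loci were higher with 6-BA and lower with DEX. Both effects use all 8 arrays, so a change in 1 group moves both, and these are not separate observations. Of the 12, 7 were well above background on at least 1 array of each group and 2 in the 6-BA group alone. They include GA20OX3 with the limits given above, UGT76C2 (1.55 and -0.995), FAF3 (1.74 and -0.64) and the glutaredoxin genes AT4G15660 (1.18 and -1.19) and AT4G15680 (1.45 and -1.12). Higher with both were 6 loci, among them ARR5, ARR9 and ARR17, well above background on at least 1 array of each group, RL1, well above background on 5 arrays, and AT2G22940 and A_84_P766924, seen with both compounds alone.

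The remaining lists had no member called adjusted over the list alone in either average effect without the replicate block, and no camera call there with the main values. For 6-BA and for DEX camera gave adjusted p = 0.234 and 0.234 for cytokinin synthesis and activation, 0.773 and 0.547 for auxin transport, 0.793 and 0.19 for the early auxin response, 0.684 and 0.344 for shoot meristem and boundary genes, 0.421 and 0.364 for ABA and drought response, 0.922 and 0.65 for ethylene synthesis, and 0.19 and 0.48 for the cell cycle. It gave 0.266 and 0.727 for nitrate uptake and assimilation, 0.266 and 0.648 for touch, wound and early stress response, 0.972 and 0.588 for heat shock, 0.0901 and 0.526 for xenobiotic response, 0.573 and 0.583 for the circadian clock, and 0.972 and 0.925 for root markers. With normexp camera placed xenobiotic response lower for 6-BA (adjusted p = 0.0177; adjusted p = 0.625 with an estimated correlation) and the early auxin response lower for DEX (adjusted p = 0.0137; adjusted p = 0.593 with an estimated correlation). For 6-BA against mock, xenobiotic response lay below other loci (median -0.83, adjusted p = 0.00291; adjusted p = 0.536 with an estimated correlation), and with normexp too (-0.51, adjusted p = 0.00172). The HD-ZIP III list had 0.285 and 0.452. For 6-BA, the HD-ZIP II, LITTLE ZIPPER, auxin synthesis, abaxial polarity and ABA receptor lists had 0.285, 0.793, 0.19, 0.134 and 0.922, and for DEX the type-B and receptor lists had 0.937 and 0.831. Of 208 tests of lists over the 8 contrasts, 44 passed camera, 34 of them with normexp too in the same direction, with 9 others newly passing there, and 0 passed with an estimated correlation, while fry, which asks whether a list moves one way on balance, passed 14. The test with an estimated correlation had so few degrees of freedom that it could hardly pass any list, so its 0 does not decide whether lists moved.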

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

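The test of probes seen in 1 treatment, the tests of cytokinin-responsive factors, the lists with normexp and the test of heat shock genes were chosen only after the results were seen, and the splits of the arrays before.

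For 4 lists the 6-BA effect differed with and without DEX by camera on the interaction term, though no member passed adjusted over the list alone. Fry passed 0 of the 26 lists for the interaction. Type-A response regulators had a median interaction of -0.29 with 0 of 9 members positive. Camera gave adjusted p = 0.0146, with adjusted p = 0.536 with an estimated correlation and 0.126 with normexp. The regulators rose less over DEX alone than over mock, with a median of 0.19 for DEX against mock. By the median they were not lower with both compounds than with 6-BA alone (0.08 for 6-BA+DEX against 6-BA). Type-B response regulators had a median of -0.20 with 1 of 7 positive (adjusted p = 0.00742; adjusted p = 0.221 with an estimated correlation; 0.128 with normexp). The 7 genes of ABA and drought response had 0.20 with 6 positive (adjusted p = 0.0257; adjusted p = 0.3 with an estimated correlation; 0.00732 with normexp). The 8 xenobiotic response genes had 0.63 with all 8 positive (adjusted p = 0.00277; adjusted p = 0.536 with an estimated correlation), but medians of -0.32 on slide 1 and 1.62 on slide 2, and -0.07 with normexp (camera adjusted p = 0.675). With normexp alone the 27 genes of the early auxin response passed too, with a median of 0.06 (adjusted p = 0.0137; adjusted p = 0.593 with an estimated correlation).

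Probes well above background on both arrays of 1 treatment and on no other array, over 2-fold brighter there than on any other, such as AT2G22940 and A_84_P766924 with both compounds, numbered 39. Of 24 pairings of arrays across the slides, 4 gave as many, the true one included, and the highest other gave 42. The 3 others keep 1 or 2 of the true pairs, and the 9 pairings with no true pair gave 23 to 37. Spots bright by accident therefore remain a candidate explanation for these probes as a set. A response to the combined treatment stays open and was not tested otherwise.

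The 8 loci called for the average 6-BA effect were matched by 3 of 35 splits of the 8 arrays into 4 and 4, the real one included, so chance cannot be excluded by this count. The highest other, 1329, parts the slides and points to a structure of the samples, and the other is the DEX split with 19, while the remaining 32 gave at most 1. For the average DEX effect, with 19, the slide split was the other of 2. Among the 18 splits that keep both slides balanced, with the replicate block, 2 gave as many as the 75 for 6-BA (highest other 500, the DEX split) and 1 as many as the 500 for DEX (highest other 75, the 6-BA split). The remaining 16 gave at most 1. The spread in each split comes from pairs of arrays. The 2 treatment splits keep the replicate pairs, while all other splits drew theirs at random, many from unlike treatments. Treatment differences can then widen the spread and lower the count, so the low counts of the other splits do not measure chance. These 18 are too few for a share under 0.05.

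Cytokinin-responsive transcription factors and effectors lay lower with DEX, with CRF2 (-0.84) and EXPA1 (-0.60) past the test adjusted over the list alone. On slide 1 alone the median was -0.24, reached by a share of 6e-04 of random lists of like brightness (slide 2 -0.41). The list was picked for its low average, which slide 1 enters, and the random lists lack the shared variation of its genes. This share therefore cannot decide whether the low signal of the slide 2 arrays with DEX is the source. After quantile normalization camera still passed the list (adjusted p = 0.0102). Camera sets the list against other loci of the same arrays, where a shift shared by an array largely cancels, so this cannot decide on scaling. The list's median was -0.19 after quantile normalization and -0.18 without for DEX against mock. For 6-BA+DEX against 6-BA it was -0.45 and -0.46, so these sizes hardly moved with this choice of scaling. Background correction remains a candidate explanation for at least part of the difference, by a limit on the median's size that was added to camera's adjusted p after both values were seen. With normexp the list's median shrank from -0.31 to -0.06, while the median of all loci was 0.08, and for DEX against mock the list turned from -0.18 to 0.19 (camera adjusted p = 0.37). For 6-BA+DEX against 6-BA, from other arrays, background correction is argued against as the whole source, since the median was -0.46 without and -0.44 with normexp (camera adjusted p = 0.00109 and 4.32e-05; adjusted p = 0.285 and 0.143 with an estimated correlation). For the average DEX effect camera still placed the list lower with normexp (adjusted p = 0.0137; adjusted p = 0.322 with an estimated correlation), which sets the genes' test statistics against those of other loci and does not measure the size. The estimated correlation (adjusted p = 0.415) leaves open whether these genes move as a set beyond their shared variation, and an effect of DEX without the fusion stays open, untested.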

How the results depend on the processing

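The replicate block with trend and robust moderation, and leaving out the DEX and 6-BA+DEX arrays of slide 2 with and without the block, were chosen after seeing the data, as were the lists with normexp. The contrasts below come in the order 6-BA, DEX and 6-BA+DEX against mock, 6-BA+DEX against 6-BA and against DEX, average 6-BA, average DEX and interaction.

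Loci called by limma numbered 0, 0, 15, 0, 0, 8, 19 and 0. With the replicate block they numbered 15, 5, 183, 9, 1, 75, 500 and 0, and with the replicate block, trend and robust moderation 14, 50, 470, 89, 11, 286, 727 and 0. After quantile normalization they numbered 9, 2, 24, 7, 4, 19, 30 and 1, with 3 cooperative loci, and the series matrix values gave the same counts. The sorted matrix values were nearly the same on every array, as quantile normalization leaves them, so the matrix is not a separate check. How it was made is not stated. Of the 15, 8 and 19 limma calls 13, 7 and 16 were among the 24, 19 and 30 after quantile normalization. The share of higher loci moved from 86.7% to 66.7% for 6-BA+DEX against mock and from 84.2% to 63.3% for the average DEX effect. The submitters' criterion gave 602, 944, 1328, 824, 594, 635, 1162 and 220. Without its fold limit, 983, 1255, 1902, 1105, 1051, 1914, 2202 and 230 of 21969 loci had an unadjusted p under 0.05. A plain unmoderated test at the submitters' criterion gave 319, 469, 531, 330, 247, 412 and 890, and has no value here for the interaction.

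For 6-BA+DEX against mock, 0 loci were called with normexp, without the filter on dim probes, with only the groups of the contrast and by the plain test after Benjamini-Hochberg, and 6 with trend and robust moderation. For the average 6-BA effect, 0 were called without the filter and 19 by the plain test after Benjamini-Hochberg. For the average DEX effect, 0 were called with normexp and 0 without the filter, 8 with trend and robust moderation, 31 among probes well above background on all 8 arrays and 2 by the plain test after Benjamini-Hochberg, AT1G32090 (1.13) and AT5G47250 (1.91). Without the filter 33595 loci were tested in place of 21969. Leaving out the slide 2 arrays with DEX gave 0 for these 3 contrasts, with and without the block. For the rest the cause was not tested.

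Each array left out gave 0 to 0 loci in every contrast and 0 to 0 cooperative loci. The calls for 6-BA+DEX against mock and both average effects thus ended without mock replicate 1 or 2, 6-BA replicate 1 or 2, DEX replicate 1 or 2, or 6-BA+DEX replicate 1 or 2. The lowest adjusted p lay between 0.0549 and 0.225 for average 6-BA, between 0.0647 and 0.212 for average DEX and between 0.074 and 0.236 for 6-BA+DEX against mock. A lone sample left in a group is assumed to vary like the other groups, and 3 residual degrees of freedom remain in place of 4. These fits lack the replicate block, and leaving out an array also unbalances the slides. No single array was left out with the replicate block, so the calls with the block were not tested in this way.

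Across loci, r between the average effects moved from 0.05 to -0.274 with normexp and 0.270 without the filter. For probes well above background on all 8 arrays, r was 0.610 for 6-BA and 0.751 for DEX with and without the other compound. Gene lists passing camera numbered 44, 46 with the replicate block, 46 after quantile normalization, 43 with normexp, where 34 of the 44 passed in the same direction, and 0 with an estimated correlation, with or without the block. With normexp 9 other lists newly passed. Besides those of the average effects and the interaction given above, these were ABA and drought response, early auxin response and auxin synthesis for DEX against mock (adjusted p = 0.0116, 0.0023 and 0.0154), auxin synthesis for 6-BA+DEX against mock (0.0164) and cytokinin degradation for 6-BA+DEX against 6-BA (0.0338). With an estimated correlation these had adjusted p = 0.322, 0.514, 0.593, 0.593 and 0.437. The median of all loci was 0.12 for DEX against mock with normexp and 0.00 without, and -0.13 and -0.03 for 6-BA+DEX against DEX.

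Of 10160 values of named loci over all settings, 9003 stayed on their side of the test, 458 no longer passed, 698 newly passed and 1 called value reversed, AT5G55450 for the average DEX effect with normexp (0.23). Values not called over all loci turned too with normexp, such as GA20OX2 (0.51) and PIL1 (0.28) for DEX against mock. With the replicate block 97 of 419 values of named loci newly passed and 0 no longer did. Among lists, camera with the replicate block newly passed heat shock (adjusted p = 0.01) and shoot meristem genes (0.0146) for DEX against mock, cytokinin degradation for average DEX (0.0372) and heat shock for the interaction (0.0266). With an estimated correlation these had adjusted p = 0.593, 0.593, 0.636 and 0.593, and the meristem median turned from -0.40 to 0.51 with normexp. It no longer passed LITTLE ZIPPER genes for 6-BA+DEX against mock (0.231) or abaxial polarity genes for 6-BA+DEX against 6-BA (0.0615). The block changed no other list's camera call. A slide or scan day block was not run because it equals the replicate number. A fit of only the contrast's groups has no value of its own for the average effects and the interaction. Signal over background limits the loci that 61.6% to 71.1% of spots could measure.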

Other observations

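The tests of this part were chosen only after the results were seen.

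Of 5 heat shock genes measured, HSP90.1 (3.90), HSP70 (3.33), HSFA2 (3.12) and HSP101 (1.17) were higher on slide 2 than on slide 1 in limma. HSP18.2 had -0.41, and each value is an average over the 4 groups. For the list camera gave adjusted p = 0.0168, and adjusted p = 0.625 with an estimated correlation. Random lists of like brightness reached the list's median of 3.12 in a share of 1e-04, the smallest the draws can give, which argues against the genes' brightness alone as the source. The list was picked for this same difference, and the random lists lack the shared variation of its genes. The share is therefore no measure of chance. Growth, harvest and scan of each replicate share the slide and cannot be told apart by design. Shoot meristem and boundary genes had a median of -0.64 between the slides (camera adjusted p = 0.00119; adjusted p = 0.617 with an estimated correlation) and cell cycle genes -0.53 (adjusted p = 0.0168; adjusted p = 0.617 with an estimated correlation). Of 13 circadian clock genes 8 differed between the slides, and they did so both ways. ELF4 (0.71) and BOA (0.60) were higher on slide 2, and the rest of the 8 were lower, among them CCA1 (-1.65) and LHY (-1.20). The list had a median of -0.72 (camera adjusted p = 0.0726, or 0.72 with an estimated correlation).

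Among 371 families formed by symbol, camera placed EIF translation initiation factors (18 measured, median 0.31, adjusted p = 4.46e-08), RPL ribosomal protein genes (22, 0.18, adjusted p = 1.89e-06) and EXPA expansins (14, 0.42, adjusted p = 1e-05) above other loci for 6-BA. It placed CIPK kinases (19, -0.19, adjusted p = 0.00415) below. For DEX it placed PUP purine permeases (11, 0.46, adjusted p = 0.0172) above and TRM genes (29, -0.24, adjusted p = 0.0184) below. With an estimated correlation each had adjusted p = 0.999.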
